A study of Homo sapiens with 6 samples.

How the data were processed

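Transcripts of 6 libraries labelled Caco2 were measured by RNA sequencing, 3 from cells infected with vector and 3 from cells infected with PIM1, and groups and replicate numbers were taken from the sample titles. The authors deposited 1 table with a count and an FPKM value per gene and library. The deposited counts are whole numbers that were not normalized, and the FPKM values were scaled by the authors for transcript length and the total of mapped fragments, per the file headers. The submitters' processing notes name fastp, HISAT2, StringTie and edgeR without versions, and how read pairs became counts, whether strand was used and which filters were applied are not given in the sources used here. Those notes also name GRCm38, a mouse assembly, whereas the table holds human gene identifiers. Of its 36049 identifiers, 94.9% (34197) are in GENCODE 29, 99.8% of these on the same chromosome and 99.5% with a start or end within 2000 bp, so the coordinates printed are on GRCh38. No gene was at 0 in all libraries, and 9302 were named by identifier only.

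Total counts of 61677430 to 71621456 per library set the counting error. No library was a copy of another: the chi-square per gene between replicates was 13.8 to 32.5 over genes with at least 100 counts, far above sampling noise. Genes were kept by filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 on the deposited counts of all 6 libraries with no covariates, since the labels give no batch. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted, with no fold minimum, and 21203 genes were tested. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F. The biological coefficient of variation was 19.2%. Group values are mean CPM ± SD with n = 3. In simulated counts for the same 21203 genes of PIM1 against Vector, single genes were changed only if their mean was at least 5 CPM. The test recovered 22% of those changed 1.25-fold, 84% of those changed 1.5-fold, and 100% of those changed 2-fold or 3-fold. Recovery of genes below 5 CPM was not simulated. Of its 176 calls, 13 were genes that had not been changed. A simulated list shift of 0.3 on the log2 scale was called by camera with the preset and with an estimated correlation. With the preset no other list was called. Genes were simulated independently of each other, so this cannot show how camera behaves where genes of a list are correlated. The shift was also larger than the absolute median change of every list called in the data except the histones.

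Genes were named by a rule fixed, like the gene lists and the tests, before the data were examined. PIM1, PIM2 and PIM3 were always named. Named as well were the 10 largest changes in each direction among called genes with a symbol, no overlap between groups and at least 5 CPM in the higher group, and up to 4 members with the smallest p of each called list, some of which are not reported here. Gene lists, 38 in number, were written from textbook knowledge, and 37 had the 5 tested members needed, the PIM kinases having 3. They were tested with camera of limma 3.58.1 with an inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 37 lists, and again with an estimated correlation. With fry it was asked instead whether the genes of a list moved one way on balance, without comparing them with other genes. Counts of members are given over all genes tested and adjusted over the list alone. The histone list held 40 symbols, older ones included, of which 16 were tested. Lists for colon epithelium, trophoblast and hepatocyte identity were added after called genes had been seen.

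Alternatives were DESeq2 1.42.0, median-ratio and total-count scaling, no filter and a filter of 5 CPM, removal of genes without a name, a fold minimum, a prior count of 0.5, a replicate block and the omission of each library. A removal of GC and length trends by offsets (natural splines with 5 degrees of freedom on GENCODE 29 transcripts), limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, and the omission of PIM1 replicate 1 with Vector replicate 2 were added after seeing the data. Principal components were taken on centred, unscaled log2 CPM of the tested genes. The trophoblast list was also refitted without each library, and the chromosome tests were repeated with the GC and length trend removed, both after the data had been seen. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and plotted with matplotlib 3.10.9. Transcript-level values were not analysed here.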

Results

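RNA sequencing was carried out on 6 libraries labelled Caco2, an established human colon adenocarcinoma line whose confluent cells take on features of absorptive enterocytes. Vector was introduced into the cells of 3 libraries and PIM1, a serine/threonine kinase gene, into the cells of the other 3. Gene counts and FPKM were available for 36049 genes. Total counts were 61677430, 68332654 and 62915370 in the Vector libraries and 62149857, 62788424 and 71621456 in the PIM1 libraries, and each library had counts for 27366 to 28417 genes. Across genes, which are not independent replicates, log2 CPM correlated between libraries at r = 0.974 to 0.977 within a group and at 0.972 to 0.977 between groups. In a principal component analysis the first component (24.3% of the variance) lay at -34.3 to -24.5 in Vector libraries and at 17.6, 64.2 and 4.5 in PIM1 replicates 1, 2 and 3. On the second (21%) these PIM1 libraries lay at -62.8, 35.9 and -14 and the Vector libraries at 9.8 to 19.5, so PIM1 replicates 1 and 2 each stood apart. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

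All 6 libraries held few intestinal transcripts and many transcripts typical of placental trophoblast. Of the 31 enterocyte and brush border genes in the table, 22 had a mean deposited FPKM below 1, and the median over the list was 0.067. The brush border protein gene VIL1 was at 0.28 ± 0.13 FPKM in Vector and 0.25 ± 0.05 in PIM1 libraries (SD, n = 3 each), and the intestinal and hepatic transcription factor gene HNF4A at 0.29 ± 0.03 and 0.28 ± 0.03. The other 9 were led by the caudal homeobox genes CDX2 and CDX1, with mean values of 33.6 and 23.5 FPKM, and EPS8L2 at 19.7 FPKM, followed by SLC15A1 at 2.8, ANPEP at 1.84 and DPP4 at 1.49 FPKM. Of 51 trophoblast genes in the table, 35 had a mean FPKM of at least 1 and 18 of at least 10. Among them were the transcription factor genes GATA3, at 74.9 to 86.5 FPKM in the 6 libraries, and TFAP2C, at 67.9 to 76.1 FPKM. The endogenous retroviral envelope gene ERVW-1, which encodes syncytin, lay between 20.8 and 31.7 FPKM, and the glycoprotein hormone alpha subunit gene CGA between 9.45 and 17.3 FPKM. The other 16 trophoblast genes had a mean below 1 FPKM, such as CSH1 (0.04), INSL4 (0.03), PSG1 (0.05) and ELF5 (0.08). The trophoblast list was written after genes changed by PIM1 had been seen, and the marker genes named here were chosen after their values were seen. Of the other cell lists, 1 of 12 leukocyte genes, 1 of 23 secretory lineage genes and 3 of 12 packaging-cell genes had a mean FPKM of at least 1. The fibroblast and endothelial list had 10 of 18 such genes, led by the collagen genes COL1A2 at 41.5 and COL1A1 at 39.97 FPKM, whereas endothelial PECAM1 was listed at 0.

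**Figure D1:**
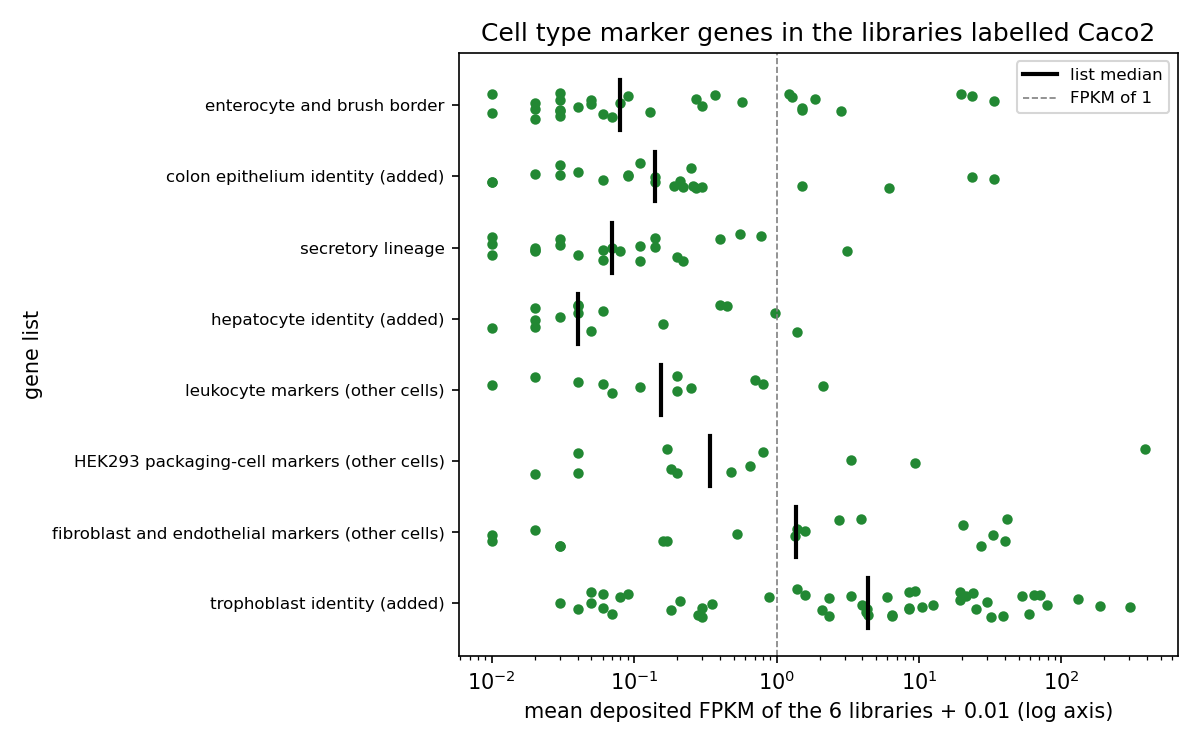
Mean deposited FPKM over the 6 libraries, plus 0.01, on a log axis for each gene of 8 cell type lists; points are genes, black bars list medians and the dashed line an FPKM of 1. The median was 0.067 FPKM for the enterocyte list and 4.36 FPKM for the trophoblast list.

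The first question was whether PIM1 transcripts were higher in the libraries labelled PIM1. PIM1 was at 896.5 ± 23.0 CPM in the PIM1 libraries and 149.5 ± 8.42 CPM in the Vector libraries (SD, n = 3 each), a 6.0-fold difference with no overlap between groups. The log2 fold change was 2.58 (SE 0.06), with an adjusted p of 9.4e-09 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In deposited FPKM the means were 279.6 ± 8.51 and 47.1 ± 2.70, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The related kinase genes PIM2 and PIM3 showed no detectable difference, with log2 fold changes of 0.01 (SE 0.16) and -0.03 (SE 0.09). PIM1 (ENSG00000137193) lies on chromosome 6 at 37170152 to 37175428 of GRCh38, and the counts do not separate introduced from endogenous transcripts.

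**Figure D2:**
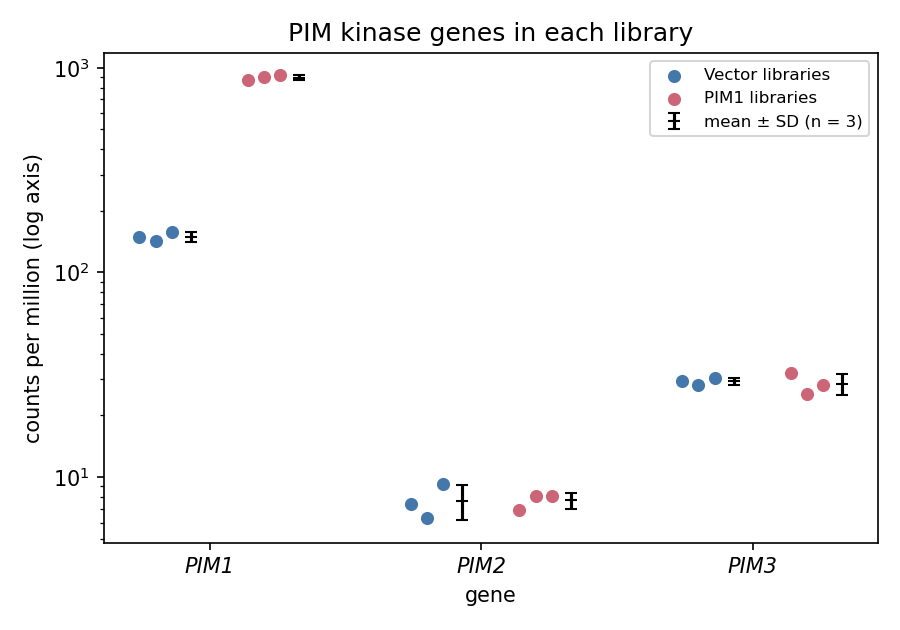
CPM, on a log axis, of PIM1, PIM2 and PIM3 in each of the 3 Vector (blue) and 3 PIM1 (red) libraries, with the mean and SD of each group in black. PIM1 lay at 142 to 158 CPM in the Vector libraries and 873 to 918 CPM in the PIM1 libraries, while PIM2 and PIM3 overlapped between groups.

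The second question was which other genes differed between the PIM1 and the Vector libraries. Besides PIM1, the largest rises among genes past 5 CPM were in the NADPH oxidase gene NOX5, the Polycomb-related gene SFMBT2, the imprinted long non-coding RNA H19 and the alkaline phosphatase gene ALPG. The largest falls were in the growth factor gene FGF9, the fatty acid translocase gene CD36, the basal keratin gene KRT5, LRATD1 and the neurotrophic factor gene GDNF. Of 21203 genes tested, 84 were higher and 121 lower, with a median absolute log2 fold change of 0.50, and 9 of the higher and 21 of the lower genes changed by at least 1 on the log2 scale.

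H19 (chromosome 11, 1995176 to 2001470) rose from 237.7 ± 4.50 to 556.9 ± 2.57 CPM, a log2 fold change of 1.23 (SE 0.05) with an edgeR adjusted p of 9.6e-07 (Benjamini-Hochberg). CDKN1C, an imprinted cyclin-dependent kinase inhibitor gene on the same chromosome arm, rose from 44.0 ± 2.85 to 73.8 ± 5.88 CPM, and ALPG rose from 52.4 ± 7.28 to 107.4 ± 4.41 CPM. NOX5 rose from 6.41 ± 2.02 to 19.3 ± 0.85 CPM and SFMBT2 from 2.60 ± 0.26 to 7.14 ± 2.19 CPM. The chemokine receptor gene CCR7, the forkhead gene FOXB1, the microtubule-associated protein gene MAP1A and the stress-induced nuclear protein gene NUPR1 completed the 10 largest rises, with log2 fold changes of 1.02, 0.79, 0.78 and 0.76. KRT5 (chromosome 12, 52514575 to 52520394) fell from 20.6 ± 1.78 to 8.99 ± 0.21 CPM, a log2 fold change of -1.20 (SE 0.10) with an edgeR adjusted p of 0.00091 (Benjamini-Hochberg). CD36 fell from 15.2 ± 0.66 to 5.58 ± 1.32 CPM, LRATD1 from 37.2 ± 5.11 to 16.6 ± 3.18 CPM, FGF9 from 6.92 ± 0.32 to 2.35 ± 0.66 CPM and GDNF from 6.48 ± 1.0 to 2.93 ± 0.06 CPM. DACH1, ANKRD1, PARM1, the planar cell polarity gene PRICKLE1 and the Wnt receptor gene FZD8 fell by 1.14, 1.10, 1.06, 1.06 and 1.03 on the log2 scale. PIM1, H19, ALPG, CDKN1C, MAP1A, NOX5, KRT5, ANKRD1 and PRICKLE1 passed the test whichever library was left out. CD36, LRATD1 and PARM1 failed only without Vector replicate 3 (edgeR adjusted p of 0.0526, 0.06 and 0.0575), and CCR7 and FGF9 failed without Vector replicate 1, 2 or 3 (up to 0.0984 and 0.102). SFMBT2 failed without any of these or PIM1 replicate 1 (up to 0.115), and DACH1 without Vector replicate 2 or 3 or PIM1 replicate 1 or 3 (up to 0.102). GDNF passed only without Vector replicate 2 (otherwise up to 0.115), and FOXB1, NUPR1 and FZD8 passed in none of the 6 fits that left out a library, with edgeR adjusted p of up to 0.226, 0.158 and 0.183. ALPG shares sequence with near-identical alkaline phosphatase copies, NOX5 overlaps SPESP1 on the same strand, and 16 of the 34 genes that passed and met the naming rule overlap a gene other than a small RNA on the other strand, so these values are uncertain as the counting is not stated to use strand.

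**Figure D3:**
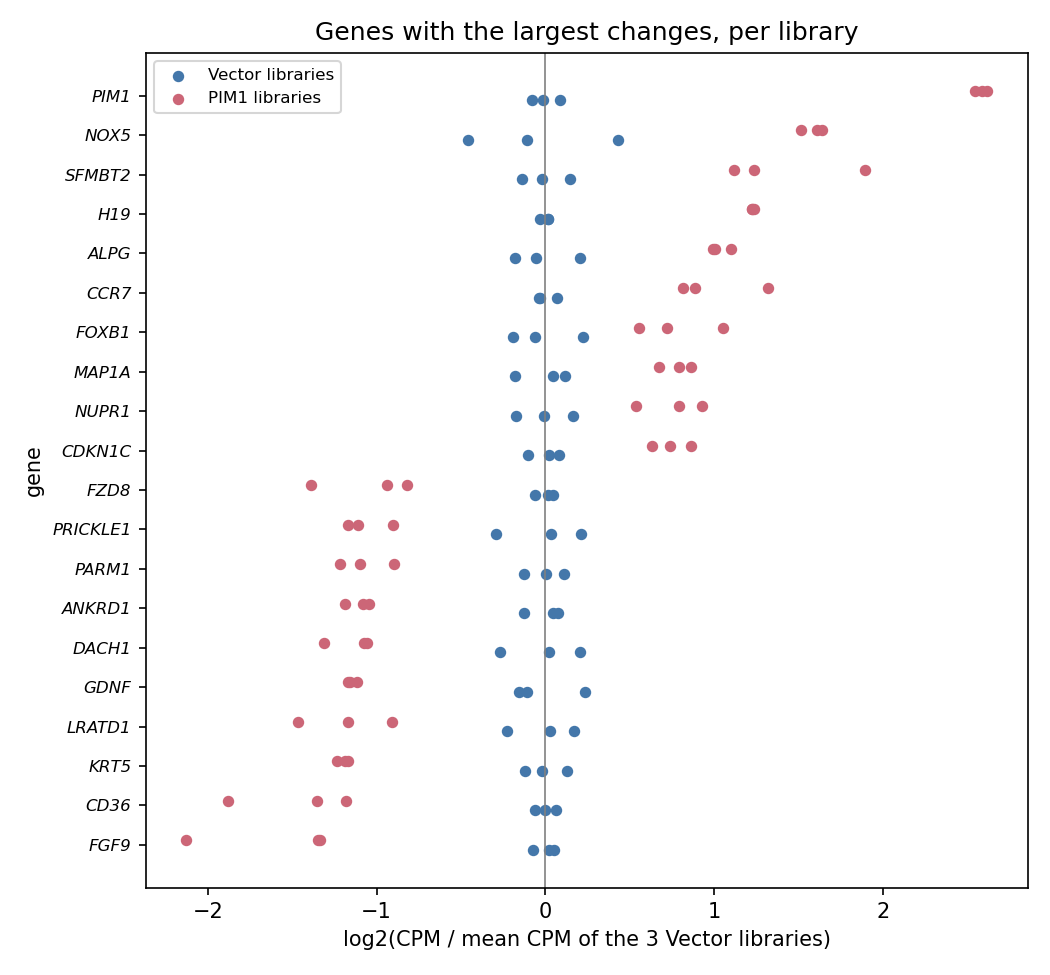
The log2 ratio of each library's CPM to the mean CPM of the 3 Vector libraries for the 10 genes with the largest rises and the 10 with the largest falls; blue points are Vector and red points PIM1 libraries. The groups do not overlap for any of the 20 genes, which the rule for naming them required, and changes run from PIM1 at a fitted log2 fold change of 2.58 to FGF9 at -1.56.

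Leaving out 1 library changed the number of calls by more than 1.5 times in each case. Without Vector replicate 1, 2 or 3 in turn, 8, 27 and 10 genes were higher and 22, 45 and 11 lower, and without PIM1 replicate 1, 2 or 3 there were 18, 35 and 15 higher and 38, 36 and 35 lower. All 205 genes kept their sign in each of these fits, which was nearly set in advance because their groups did not overlap. With DESeq2 the counts were 498 higher and 418 lower, and with no filter on low counts 20 and 29.

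Genes of the integrated stress response and the unfolded protein response were higher in the PIM1 libraries as lists. Of 31 genes of the integrated stress response, the amino acid and translation stress program of the transcription factor ATF4, 27 had a log2 fold change above 0 and the median was 0.18. NUPR1, the mTORC1 inhibitor gene DDIT4 (0.45), the mitochondrial gluconeogenic enzyme gene PCK2 (0.41), the cystine transporter gene SLC7A11 (0.38) and the tryptophanyl-tRNA synthetase gene WARS1 (0.38) rose over all genes tested, and 15 rose adjusted over the list alone. Camera called the list with an adjusted p of 2.8e-09 (Benjamini-Hochberg), and it had an adjusted p = 0.695 with an estimated correlation. Of 23 unfolded protein response genes, 22 were above 0 with a median of 0.14. The endoplasmic reticulum chaperone genes DNAJC3 (0.34) and HSPA5 (0.29) rose over all genes and 5 rose adjusted over the list alone, while CANX had a log2 fold change of 0.17 and DNAJB9 of 0.35 without passing. Its camera adjusted p was 1.0e-05 (Benjamini-Hochberg), and its adjusted p = 0.695 with an estimated correlation. Of 20 heat shock genes, the cochaperone gene BAG3 (0.32) and HSPA1A (0.33) rose over all genes and 6 rose adjusted over the list alone, with a camera adjusted p of 0.000657 and an adjusted p = 0.70 with an estimated correlation. HSPA1A and HSPA1B (0.28, not passing) are near-identical copies between which reads can be split. Camera called these 3 lists in each fit that left out 1 library. Of the 9 single genes that rose, none passed without Vector replicate 1 or 3 or PIM1 replicate 1 or 3, with edgeR adjusted p of up to 0.226, while PCK2, DNAJC3 and HSPA5 passed without Vector replicate 2 and SLC7A11, WARS1, DDIT4 and DNAJC3 without PIM1 replicate 2.

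Genes of G1/S progression and DNA replication were lower in the PIM1 libraries as a list. Of 30 genes, 28 had a log2 fold change below 0 and the median was -0.16, yet none passed over all genes tested. Adjusted over the list alone, 15 fell and 1 rose. The nucleotide synthesis gene TYMS had a log2 fold change of -0.35 (SE 0.08), the replication licensing gene CDT1 -0.30 (SE 0.07) and the transcription factor gene E2F2 -0.49 (SE 0.13). The camera adjusted p was 4.1e-08 (Benjamini-Hochberg), and the adjusted p = 0.70 with an estimated correlation. The list was called in each fit that left out 1 library. Replication-dependent histone transcripts, most of which lack a poly(A) tail and so also follow RNA selection, were higher as a list. Whether this bears on the cell cycle was not tested. Of 16 histone genes tested, 13 were above 0 with a median of 0.36, none passed over all genes and 1 rose adjusted over the list alone. H2BC5 was at 7.08 ± 0.48 CPM in PIM1 against 4.30 ± 0.80 CPM in Vector libraries. The most abundant member, H2BC12, was nearly level at 27.7 ± 0.76 against 27.2 ± 1.81 CPM (log2 fold change 0.03). Others, such as H1-5 at 0.17 against 0.23 CPM, lay near the floor. Camera gave the histone list an adjusted p of 0.0212, and it had an adjusted p = 0.70 with an estimated correlation. Without Vector replicate 1, Vector replicate 3 or PIM1 replicate 1 the camera adjusted p of the histone list was 0.0975, 0.0537 and 0.1. Of the genes of G2/M and mitosis, only the kinesin gene CENPE rose, and camera did not call that list (adjusted p = 0.855).

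Wnt target and epithelial-mesenchymal transition genes were lower as lists. Of 27 Wnt target and intestinal stem cell genes, LEF1, a transcription factor of the Wnt pathway, fell by 0.67 on the log2 scale, the ephrin receptor gene EPHB2 by 0.80 and the homeobox gene PROX1 by 0.62, and 5 fell adjusted over the list alone. BMP4 had a log2 fold change of -0.30 without passing. With camera the adjusted p was 0.046 (Benjamini-Hochberg), with an adjusted p = 0.70 with an estimated correlation, and without Vector replicate 1, Vector replicate 3, PIM1 replicate 2 or PIM1 replicate 3 it was 0.0858, 0.24, 0.0679 and 0.0725. No filter on low counts gave a camera adjusted p of 0.0512, and the replicate block gave 0.0726. The median log2 fold change of the list, -0.10, was -0.05 without Vector replicate 3 and -0.04 without PIM1 replicate 2. When 1 library was left out, LEF1 failed only without Vector replicate 3 (edgeR adjusted p of 0.06), EPHB2 passed only without Vector replicate 2 or PIM1 replicate 2 (otherwise up to 0.125) and PROX1 in no case (up to 0.178). Of 26 genes of epithelial-mesenchymal transition, 2 fell over all genes tested, among them the actin-binding protein gene TAGLN, which fell by 0.47 on the log2 scale. Adjusted over the list alone 8 fell and 1, ITGA5 (0.26), rose, and TGFBI (-0.41) and CALD1 (-0.29) did not pass over all genes. VIM (-0.10), SNAI1 (0.32), SNAI2 (-0.50), ZEB1 (0.11) and ZEB2 (-0.02) did not pass in either adjustment. For this list camera gave an adjusted p of 0.0032, with an adjusted p = 0.70 with an estimated correlation, and without PIM1 replicate 2 it was 0.768. The median log2 fold change, -0.12, was -0.21, -0.19 and -0.07 without Vector replicate 1, 2 and 3 and -0.24, -0.01 and -0.36 without PIM1 replicate 1, 2 and 3, and -0.26 with a minimum of 5 CPM or the replicate block. TAGLN passed only without PIM1 replicate 3 (otherwise an edgeR adjusted p of up to 0.214). Camera did not call the list of fibroblast and endothelial genes (adjusted p = 0.334), of which none passed over all genes, while the collagen gene COL3A1 (-0.34) and the proteoglycan gene LUM (-0.44) fell adjusted over the list alone.

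Genes of energy metabolism and oxidative stress were slightly higher as lists. Of 32 glycolysis and hypoxia genes, the hexokinase gene HK2 rose by 0.34 on the log2 scale, 6 rose adjusted over the list alone, and the median was 0.06, or 0.10 without Vector replicate 3 or PIM1 replicate 1. PFKP (0.30), SLC16A3 (0.24) and EGLN3 (0.44) did not pass over all genes. Camera called the list with an adjusted p of 0.0035 (Benjamini-Hochberg) and an adjusted p = 0.70 with an estimated correlation, also when any 1 library was left out, whereas HK2 passed in none of those fits (edgeR adjusted p up to 0.202). Of 41 nuclear-encoded respiratory chain genes, 32 were above 0 with a median of 0.07 and none passed, including COX6B1 (0.17), COX6A1 (0.13), NDUFA1 (0.33) and SDHB (0.13). The camera adjusted p was 0.0119, with an adjusted p = 0.758 with an estimated correlation, and without Vector replicate 1, Vector replicate 3 or PIM1 replicate 2 it was 0.0988, 0.153 and 0.63. The median was 0.02 without PIM1 replicate 2 and 0.11 without Vector replicate 2. Of 28 NRF2 and glutathione genes, SLC7A11 rose, which the integrated stress response list also holds, and adjusted over the list alone 2 rose and the glutathione peroxidase gene GPX2 fell. HMOX1 (0.24) and AKR1C2 (0.31) did not pass over all genes, nor did GPX2 (-0.75). For this list the camera adjusted p was 0.0414, with an adjusted p = 0.70 with an estimated correlation, and without Vector replicate 1, Vector replicate 3 or PIM1 replicate 2 it was 0.157, 0.143 and 0.256. With all libraries kept, the camera adjusted p was 0.266 with no filter on low counts and 0.0726 with the replicate block.

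Of 20 antigen presentation genes, 15 had a log2 fold change below 0, the median was -0.16 and none passed over all genes or adjusted over the list alone. ERAP1 (-0.32), HLA-F (-0.52) and TAP1 (-0.45) were among the members with the smallest p, and reads of HLA-F can be shared with other members of its family. Its camera adjusted p was 0.042, with an adjusted p = 0.70 with an estimated correlation, and without Vector replicate 2, Vector replicate 3, PIM1 replicate 1 or PIM1 replicate 2 it was 0.111, 0.0537, 0.189 and 0.232. The call of this list also ended with no filter on low counts, a minimum of 5 CPM or the replicate block (camera adjusted p of 0.0572, 0.0509 and 0.0545). In all, camera called 11 of 37 lists, 7 higher and 4 lower, and with an estimated correlation it called none, although the integrated stress response and unfolded protein response lists had unadjusted p of 0.0309 and 0.0376.

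**Figure D4:**
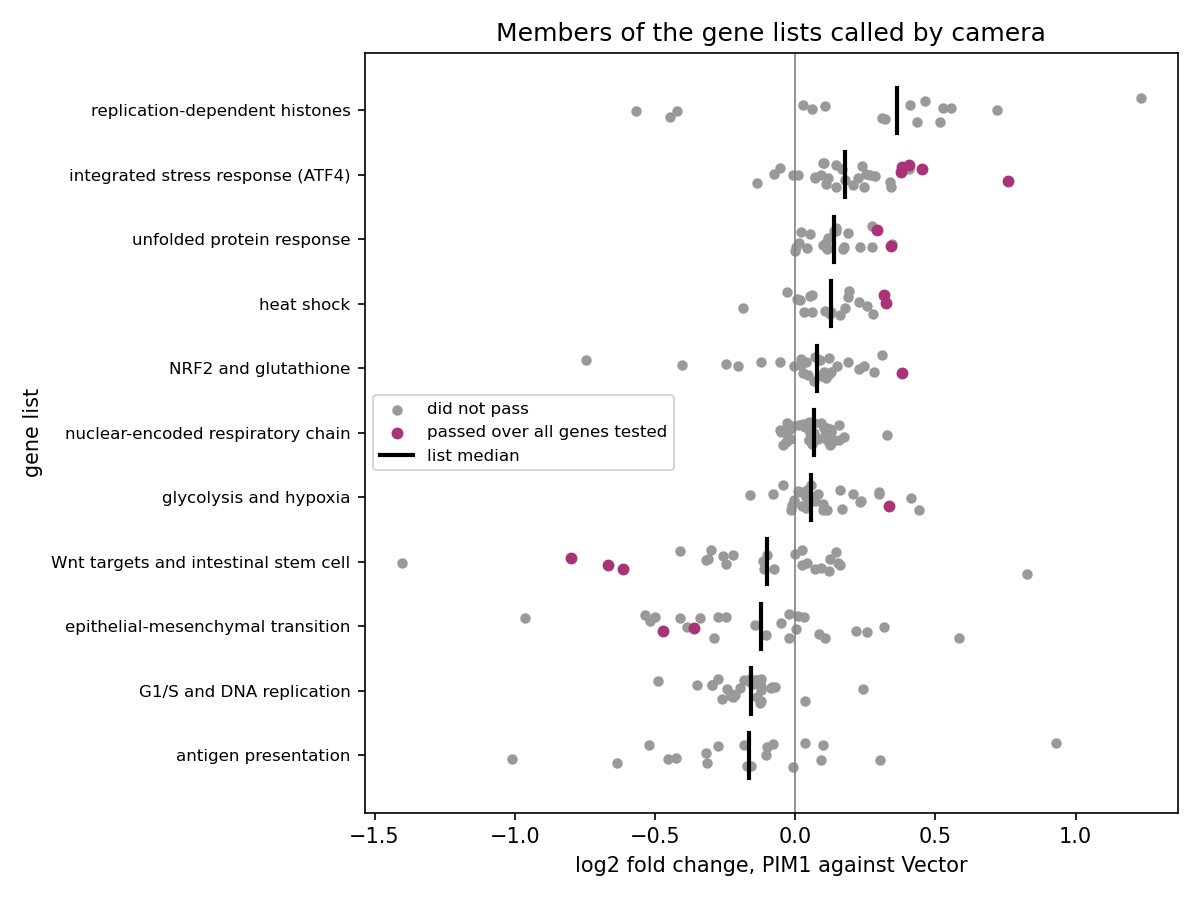
Log2 fold change, PIM1 against Vector, of each tested member of the 11 gene lists called by camera; red points passed the test over all genes, grey points did not, and black bars are list medians. Medians ran from 0.36 for the histone list to -0.16 for the antigen presentation list.

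Several lists of functions tied to PIM1 in the textbook view were not called by camera, unlike that of G1/S progression, which was lower. Of MYC targets and ribosome biogenesis genes (adjusted p = 0.253), only the transferrin receptor gene TFRC rose (0.35), of the JAK-STAT list (0.922) only SOCS2 fell (-0.55), and of the BCL2 family (0.855) and cytosolic ribosomal proteins (0.506) none passed. Camera did not call the lists of p53 targets (0.118), ERK pathway feedback (0.123), TGF-beta targets (0.0797), YAP targets (0.444), NF-kB (0.205), interferon-stimulated (0.338) or immediate-early genes (0.444). Within these, SPRY2 (-0.88) and EPHA4 (-0.50) of the ERK list, BAMBI (-0.50) and ID1 (-0.44) of the TGF-beta list and ANKRD1 of the YAP list fell. Among metabolic lists, fatty acid synthesis had an adjusted p of 0.0725 in camera with SCD raised (0.26), cholesterol synthesis 0.205 with SC5D raised (0.39), and fatty acid oxidation and PPAR targets 0.334 with CD36 lowered. Camera gave 0.59 for xenobiotic and bile acid metabolism, 0.652 for metallothioneins and 0.864 for autophagy and lysosome. For cell identity it gave 0.334 for the enterocyte list, of which CDX2 fell (-0.40), 0.718 for the secretory lineage and 0.506 for epithelial junctions, of which CGN (-0.33) and PKP2 (-0.32) fell. Camera gave 0.981 for leukocyte markers, 0.235 for packaging-cell markers, of which CRABP2 rose (0.27), 0.181 for mitochondrially encoded genes and 0.235 for nuclear-retained and small RNA, of which none passed over all genes and MALAT1 (0.32) and KCNQ1OT1 (0.40) rose adjusted over the list alone. Mitochondrially encoded genes took 7.6% to 8.1% of counts in the Vector and 7.4% to 7.9% in the PIM1 libraries. The median, mean and test differed in sign for 6 of these lists, namely enterocyte, YAP, BCL2 family, G2/M, JAK-STAT and leukocyte. The single genes given for lists that were not called were named because so few passed, after their values were seen.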

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

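The number of called genes depended on the processing. Each of the 205 called genes that was tested in an alternative kept its sign there, but the groups overlapped for none of these genes. Leaving out or rescaling libraries could then hardly turn a sign, so the kept signs say little about direction. PIM1 kept a log2 fold change of 2.55 to 2.63 and its call in all alternatives. Under the alternatives set beforehand, the 84 higher and 121 lower genes became 498 and 418 with DESeq2 (82 and 117 of the original genes among them), 146 and 182 with a minimum of 5 CPM, 20 and 29 with no filter on low counts, which adds genes to the adjustment, and 9 and 21 with a log2 fold change of at least 1. The fit with the replicate block gave 62 and 73. Deviations of same-numbered libraries correlated at 0.054, 0.102 and -0.026, and only number 2 correlated best with its own number. These values show no clear pairing by number, but they had no reference for chance, so a shared batch cannot be excluded. Leaving out each library in turn, with fewer samples in the fit, gave 8 to 35 higher and 11 to 45 lower genes. Among the alternatives added after seeing the data, removal of the GC and length trend gave 182 and 196, including all 205. Limma on deposited FPKM gave 63 and 101, with 51 of the 80 higher and 80 of the 102 lower original genes that it tested. Omission of PIM1 replicate 1 with Vector replicate 2, which lay at opposite ends of the GC trend, gave 3 and 4. The cause of the changes with DESeq2, the CPM minimum and the trend removal was not tested. The number of lists called, 11 in the original fit, was 0 with an estimated correlation and 6 to 13 when a library was left out. It was 7 without Vector replicate 3 and 6 without PIM1 replicate 2. These totals can include lists that the original fit did not call. Without Vector replicate 3 the Wnt, antigen presentation, NRF2, respiratory chain and histone lists were no longer called. The replicate block left 8 lists, and with it or a minimum of 5 CPM the median of the epithelial-mesenchymal list went from -0.12 to -0.26, by more than 1.5 times, as that of no other called list did under a setting that kept all libraries. With fry, which asks another question, whether the genes of a list move one way on balance and not how they compare with other genes, 2 lists passed, the integrated stress response and the unfolded protein response (adjusted p of 0.0494 each). Over the other settings, 64 genes that met the naming rule gave 1076 values. Of these, 858 were counted as staying on their side of the threshold, 175 lost and 43 gained a call. The 858 include values under the alternative prior count, which gave a change but no test. Changes of direction were counted only for genes called in the original fit, and there were 0. The uncalled PIM2 and PIM3 did change sign, with log2 fold changes of -0.11 to 0.17 and -0.15 to 0.04 over these settings. The 11 lists gave 187 values, those of fry included, of which 140 stayed, 47 lost the call and 0 changed direction. Depth alone did not set which calls were lost, as HSPA1A, at 163 CPM in PIM1 libraries, and FZD8, at 2.74 CPM, both passed in no fit that left out a library. The alternatives on transcripts and on a pseudocount for the count test were not run, since the table gives genes and the test uses none.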

Other observations

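Among the 116 genes lower in the PIM1 libraries that had a Gene Ontology annotation in the deposited table, 13 terms were over-represented. Animal organ morphogenesis held 9 of them against 1.1 by chance, among them CDX2, the glypican gene GPC3 and the bone morphogenetic protein gene BMP2, and angiogenesis held 11 against 1.79, including the ephrin gene EFNB2 and the chemokine receptor gene ACKR3 (Benjamini-Hochberg adjusted p of 0.00227 each, one-sided hypergeometric test). Next came cellular response to amyloid-beta (adjusted p of 0.00464), presynaptic membrane (0.00698), amyloid-beta binding (0.0105), positive regulation of cell migration (0.0125) and axon guidance (0.0141), and the ephrin receptor gene EPHB2 belonged to all 7 of these terms. Anterior/posterior pattern specification, with the homeobox genes HOXA7 and HOXB3, did not pass (0.0938). GPC3 fell from 180.4 ± 3.16 to 103.8 ± 4.60 CPM, with an edgeR adjusted p of 0.000231. Of 2618 terms with 15 to 300 genes tested per direction, 0 passed for the higher genes, whose smallest p, 0.000279 for cellular response to unfolded protein (BAG3, HSPA1A and HSPA5), had an adjusted p of 0.461. The hypergeometric test treats genes as independent and takes the called genes as given, so its adjusted p-values leave out how unstable the calls were. When 1 library was left out, 11 to 45 genes were lower. EPHB2 passed in 2 of those 6 fits. The genes were named after their values were seen.

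The tests on cell identity, on copy number, on chromosomes, on ontology terms, on the trophoblast list with its omissions of libraries, and on the GC and length trend were chosen after the patterns they bear on had been seen, while that on other splits of the libraries was set before. For the GC and length trend, the bounds for the lower calls on 13 with the higher calls on 19 and for H19 and CDKN1C were set after these patterns were seen but before the trend was removed, and that for the lack of lower genes on 19 after. Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 of 10, gave as many as 205 calls. The highest other split gave 2, and 10 splits are too few for a share under 0.05.

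The first pattern was the low level of most intestinal transcripts and the presence of placental transcripts in all 6 libraries. The deposited normalization did not hide intestinal genes, as the median raw count of the enterocyte list was at most 34 in any library. A minority of trophoblast-like cells in an intestinal culture is argued against too, since a majority of intestinal cells would bring its own abundant transcripts and the median FPKM of 23 colon epithelium genes was at most 0.2 in any library. A culture of trophoblast-like rather than intestinal identity is consistent with the data, as 68.6% of the trophoblast list but 17.4% of the colon epithelium and 6.7% of the hepatocyte list had a mean FPKM of at least 1, with XAGE3 at 301, PEG10 at 131 and GATA3 at 78.9 FPKM, but so did 55.6% of the fibroblast and endothelial list. This is a hypothesis from transcripts alone: no genotype was tested, no reference profile of Caco2 was used here, 1 trophoblast gene (LIN28B) is also on the packaging-cell list, and ALPP and other members had been seen among called genes.

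The second pattern was the chromosomal position of calls. Chromosome 13 held 10 lower genes against 2.4 expected (Fisher's exact test, adjusted p = 0.00626 over chromosomes and directions), among them FGF9 and DACH1, and chromosome 19 held 0 lower genes against 8.2 expected (adjusted p = 0.00879) and 12 higher genes against 5.7 (adjusted p = 0.213). Libraries differed in their trend with GC content, with Spearman correlations of -0.284 to 0.183 in Vector and -0.22 to 0.19 in PIM1 libraries, but removing that trend kept 100% of the 22 lower calls on 13 and higher calls on 19. The lack of lower genes on 19 also held without the trend, with 1 lower gene against 13.5 expected (adjusted p = 0.00111), as did the excess on 13, with 12 against 3.8 (adjusted p = 0.0102). Loss of a copy of chromosome 13 is argued against, because 191 of its genes above 8 CPM had a median log2 fold change of -0.0181 (95% bootstrap interval -0.0433 to 0.0027), against a median of -0.659 for the called ones. What remains open is a regulatory difference between PIM1 and Vector or changes in smaller segments. For 19 the small shift of its 687 genes above 8 CPM, whose median log2 fold change was 0.03, is open too. Chromosomes 9 and 17 had close medians of 0.0308 and 0.0254, with 1 lower gene against 4.7 expected and 8 against 7.5. Chance also remains open, since Fisher's test treats genes as independent and was chosen after the pattern was seen. FGF9 and DACH1 passed in only 3 and 2 of the 6 fits that left out a library.

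The third pattern was the rise of H19 and CDKN1C, imprinted genes of separate domains of the 11p15.5 cluster, while IGF2, next to H19, stood at 8716 ± 265 CPM in PIM1 and 8776 ± 337 CPM in Vector libraries (log2 fold change -0.01). PHLDA2 and KCNQ1OT1, of the domain of CDKN1C, had log2 fold changes of 0.58 and 0.40 without passing (edgeR adjusted p of 0.0618 and 0.127, Benjamini-Hochberg). MALAT1 (0.32), which shares the list of nuclear-retained RNA with KCNQ1OT1, also lay above 0, whereas NEAT1 (-0.10) and MEG3 (-0.04) of that list did not. A gain of this end of the chromosome is argued against, because 15 genes within 1 Mb of H19 had a median log2 fold change of -0.0396 (95% bootstrap interval -0.0957 to 0.117), below the bound of 0.373 set from the CDKN1C change. The GC and length trend is argued against too, since its removal kept 98.3% of the CDKN1C and 98.6% of the H19 change. A regulatory change of imprinted genes with PIM1 remains a hypothesis, and allelic expression was not measured.

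A further hypothesis was that trophoblast genes rise together with PIM1: of 47 tested, 34 had a log2 fold change above 0 with a median of 0.155. GATA2, ALPP, DLX3, HSD3B1 and PSG6 rose and no member of the list passed as lower. HAND1 (-0.20) and TP63 (-0.21) lay lower in all 3 PIM1 libraries without passing (edgeR adjusted p of 0.224 and 0.25). PSG6 lay at only 0.29 ± 0.17 CPM in Vector and 1.65 ± 0.24 CPM in PIM1 libraries, and no other PSG gene tested passed. ALPP is among the alkaline phosphatase copies near-identical to ALPG, so their rises may not be separate. In 15 of the 34 all 3 PIM1 libraries lay above all Vector libraries, and in 6, such as ERVFRD-1 and CYP19A1 at 152.9 and 99.3 CPM, only PIM1 replicate 1 did, while replicates 1, 2 and 3 were the highest of the PIM1 libraries in 21, 10 and 3. Without PIM1 replicate 1 the median was 0.0604, with a camera p of 0.000615 and a p of 0.0795 with an estimated correlation. Camera gave p = 1.84e-05 with the preset and p = 0.078 with an estimated correlation, so the hypothesis is neither established nor excluded, and genes of this list had been seen among the calls before it was written. The colon epithelium list lay the other way, with 2 of 16 above 0, a camera p of 0.0125 and a p of 0.0553 with an estimated correlation. Its camera p was 0.0948 without Vector replicate 3 and 0.0787 without PIM1 replicate 3. CDX2 (-0.40) was the only member of the colon list to pass over all genes, and it was left off the trophoblast list. Only 4 of the 23 genes of the colon list in the table had a mean FPKM of at least 1, so its signs come mostly from genes near the floor. The hepatocyte list, with 1 such gene of 15, had a camera p of 0.47.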
